A study of Homo sapiens with 7 samples.

How the data were processed

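Processed peak lists of 7 ATAC-seq libraries of H1 human embryonic stem cells and their derivatives were analysed, 1 list per library and none pooled over replicates. Per the labels' protocols, nuclei were treated with the transposase, the tagmented DNA was amplified and size selected, and paired ends were read on an Illumina NextSeq500. Per the submitters' processing notes, the genome build was hg38 and DiffBind was used, without a version. The tokens in the deposited file names record trimmed and sorted reads, removal of duplicates and of mitochondrial reads, Tn5 cut sites, a p limit of 0.01, a limit of 300000 peaks and a further filter. The aligner, the peak caller and their versions are not given in the sources used here. The names of the peaks run to 300000 in every library, so that the limit on number, and not the p limit, ended each list, and 626 to 1492 peaks of each were removed by the further filter.

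Each deposited peak carries a fold enrichment of its summit over a background (a ratio), which was used as the authors' value to describe peaks. That background is local to the peak in its own library and can exceed the genome-wide background given below. The fold therefore does not order summits by their height. Each also carries the deposited −log10 p and −log10 q, which grow with depth, and −log10 p was used to rank the regions within a library. The deposited score column is a display value derived from −log10 p and was not used. No fold or rank was tested between libraries, since each is relative to its own library.

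Depth was not given as a read number. For every region the fold enrichment and −log10 p could be written as the ratio (P + 1) / (L + 1) and the Poisson tail beyond P at mean L with a whole number P, in 100% of regions of each library within 0.001 of −log10 p. P was taken as the summit pileup of cut sites, and the most frequent L among the weaker regions as the genome-wide background, which measures depth. The background ran from 2.11 in hESC replicate 1 to 7.94 in hDE replicate 2, a range of 3.76 times. The weakest deposited −log10 p ran from 2.23 to 8.86, the highest in hDE replicate 2, where the limit on number removed the most weak peaks.

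Groups and replicate numbers were taken from the sample titles. Overlapping peaks of a library were merged to regions and ranked by their highest −log10 p. The top 50,000 regions of each library were called strict, and strict regions of all libraries on chromosomes 1 to 22 and X were merged by an overlap of at least 1 bp into the universe of regions. A region was absent from a library where it overlapped none of its deposited peaks. Gained regions were strict in all libraries of the later stage and absent from all of the earlier, lost regions were the reverse, and stable regions were strict in all libraries of both. The comparisons were hESC to hDE, hDE to hAFE, hAFE to hPFE and hESC to hPFE. The spread between replicates was measured as the number of regions strict in 1 replicate and absent from the other, beside the same number between stages. No peak of a replicate had the same position and fold as one of its partner.

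Similarity was tested with an exact permutation test over all divisions of the libraries into 3 pairs and 1. Genes were taken from the RefSeq table of GRCh38.p14, the build of the files, with 19974 protein-coding genes on the chromosomes used. The table gives gene spans without strand, exons or transcripts. The plan called for transcription start sites, and either end of the gene was used in their place, a change made after the data were examined. Promoters, exons, introns and untranslated regions were therefore not told apart. A region was assigned to the gene with the nearest end within 100 kb, and lay near a gene end within 1 kb. Location was compared with two-sided Fisher's exact tests.

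The 18 gene lists, with 437 entries of 372 genes, were fixed before the data were examined, and 361 of the genes had at least 1 region. The 3 symbols that had changed were matched through synonyms. For each list, comparison and direction, the number of gained or lost regions was set against 100,000 random lists drawn from the 17859 genes with a region, matched in 20 strata of the number of regions per gene, two-sided, with Benjamini-Hochberg adjustment over 144 tests and a threshold of 0.05. The test was checked on simulated data with seeded lists. A list of 28 mesenchyme and fibroblast genes was written after the data were examined and before its own test.

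The genes named were set by a rule: in each list that passed, the 4 genes with the most regions in that direction, for each comparison the 5 genes with the most gained and the 5 with the most lost regions, ties by the strongest region, and always the stage markers (POU5F1, NANOG, SOX2, SOX17, FOXA2, GATA4, GATA6, EOMES, CXCR4, PAX9, PAX1, TBX1, EYA1, HOXA3 and NKX2-3, and 1 more that is not reported here). Regions given by position are the strongest gained or lost region of a named gene, with 1-based coordinates. The tests, lists, alternatives and rules were otherwise fixed before the data were examined.

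The alternatives were 25,000 or 100,000 strict regions, a threshold on −log10 q, absence from the top 100,000 regions, an overlap of 50% of the shorter region, windows of one fixed width around the summit, each replicate left out, a replicate block, gene ends within 500 bp or 2 kb, genes within 20 kb or any gene within 50 kb, and Fisher's exact test on regions. Added after the data were examined were absence below 4 times the background, a strict summit of at least 10 times the background, and lists from regions over 1 kb from gene ends. A search for transcription factor motifs was planned and not made, since no genome sequence was used here. Analyses were run with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.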

Results

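Chromatin accessibility was profiled by ATAC-seq, which marks open chromatin by the sites where the Tn5 transposase inserts sequencing adapters. The cells were H1, an established line of human embryonic stem cells, taken at 4 stages of a stepwise differentiation towards the endoderm of the pharynx. The stages were undifferentiated stem cells (hESC, 2 libraries), definitive endoderm (hDE, 2 libraries), anterior foregut endoderm (hAFE, 2 libraries) and pharyngeal foregut endoderm (hPFE, 1 library). The pharyngeal endoderm is the embryonic source of the thymus and the parathyroid glands, and the comparisons ask which chromatin opens and closes on the way to it. The hESC and hDE libraries are labelled as re-analysed from an earlier series, and the hAFE and hPFE libraries are not. Between 298508 and 299374 peaks were deposited per library. The genome-wide background recovered from the peak values, which grows with depth, was 2.11 and 4.62 counts in hESC replicates 1 and 2, 4.58 and 7.94 in hDE, 2.22 and 3.85 in hAFE, and 5.66 in hPFE. The weakest deposited summit of a library lay between 2.47 and 3.78 times its background. A region called absent below is one without a deposited peak in that library. This is not a fixed level of signal, since p depends on the local background and the lists were limited in number and filtered. The 50,000 strongest regions of a library are called strict, and the merged strict regions of all 7 libraries made 129726 regions, of which 69.3% had an end of a protein-coding gene within 100 kb.

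Libraries of the same stage shared more of their open chromatin than libraries of different stages. The Jaccard index of the strict regions, shared bases over covered bases, was 0.497 between the hESC replicates, 0.495 between the hDE replicates and 0.570 between the hAFE replicates. Its mean was 0.521 over the 3 pairs within a stage and 0.350 over the 18 pairs between stages, which ranged from 0.244 to 0.432. The difference of 0.171 was the highest among all divisions of the 7 libraries into 3 pairs and 1 (one-sided exact permutation test, p = 0.00952, the smallest this design allows), and the next highest was 0.105. Each of the 18 values between stages lay below the 3 values within. The hPFE library shared most with the hAFE libraries (0.347 and 0.382) and least with hDE replicate 2 (0.244). The labels do not say whether replicates are separate cultures, so this p and every replicate range below measure only the spread between these libraries, which may be technical.

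**Figure D1:**
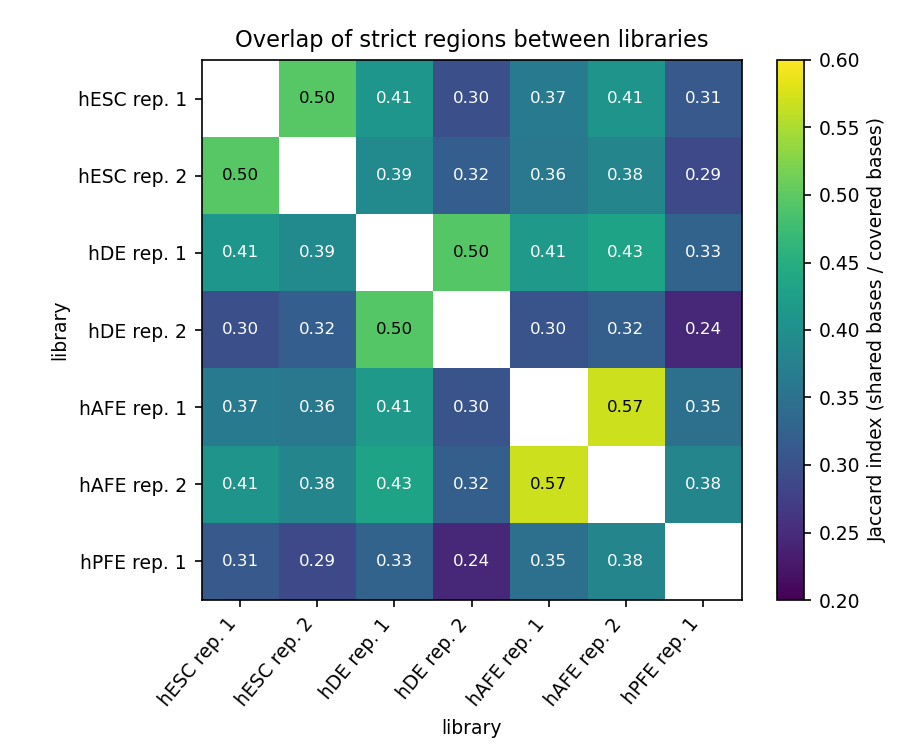
Jaccard index of the strict regions for each pair of the 7 libraries (shared bases over covered bases, colour and number in each cell, diagonal left blank). The 3 replicate pairs lie between 0.495 and 0.570, above the highest pair between stages at 0.432.

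From hESC to hDE, more regions were gained than lost. In all, 7050 regions were gained, meaning strict in both hDE libraries with no peak in either hESC library, and 1497 were lost, meaning the reverse, beside 20463 that were strict in all 4 libraries. The hESC libraries were shallower (background 2.11 and 4.62, against 4.58 and 7.94 in hDE), which makes absence from hESC easier and may widen this excess. Between hESC replicate 2 and hDE replicate 1, of similar background (4.62 and 4.58), 9915 regions opened and 6598 closed. The transcription factors of endoderm formation EOMES, GATA6 and FOXA2 had 3, 2 and 1 gained regions, and CXCR4, a surface marker of definitive endoderm, had 1. The strongest at EOMES lay on chromosome 3 from 27714040 to 27714668 (hg38), 1285 bp outside the gene, with fold enrichments of 5.97 and 6.51 in the hDE libraries. The strongest at GATA6 lay 10010 bp outside the gene, on chromosome 18 from 22158993 to 22159579, with fold enrichments of 11.8 and 16.9. These folds are over the local background. Against the genome-wide background the summits were 44.6 and 78.6 times as high at EOMES and 28.2 and 48.1 times at GATA6. PAX9, a transcription factor of the pharyngeal pouches, had 3 gained regions at this stage. Among all genes the most gained regions were at PCSK5, a proprotein convertase, with 6, and at SPOCK3, the semaphorin coreceptor gene NRP1, the transcriptional repressor gene PRDM1 and MITF, with 5 each. The PRDM1 region lay inside the gene on chromosome 6 from 106102854 to 106103969, with fold enrichments of 11.3 and 15.7. POU5F1, SOX2 and EYA1 had 1 lost region each. The one at POU5F1, the gene of the pluripotency factor OCT4, lay 9759 bp outside the gene on chromosome 6 from 31180441 to 31181002, with fold enrichments of 6.43 and 16.7 in the hESC libraries and no peak in the other 5. The genes with the most lost regions, 2 each, were ZMIZ1, SH3BGR, CDS1, EBF1 and DPYSL2. NANOG, SOX17, GATA4, PAX1, TBX1, HOXA3 and NKX2-3 had none.

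The change from hESC to hDE exceeded the differences between replicates. Between single libraries, 9915 to 16841 regions were strict in an hDE library and absent from an hESC library, and 5637 to 7162 were strict in hESC and absent from hDE. Between replicates the same count was 1040 and 2137 in hESC and 61 and 1201 in hDE. No exact test of 2 libraries against 2 can pass a threshold of 0.05, so these counts have no p. The number gained was 12917 without hDE replicate 1, and the number lost was 3948 and 4235 without hESC replicates 1 and 2 and 2267 and 2712 without hDE replicates 1 and 2. With 25,000 strict regions per library the numbers were 2465 and 287, and with 100,000 they were 17358 and 6717.

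**Figure D2:**
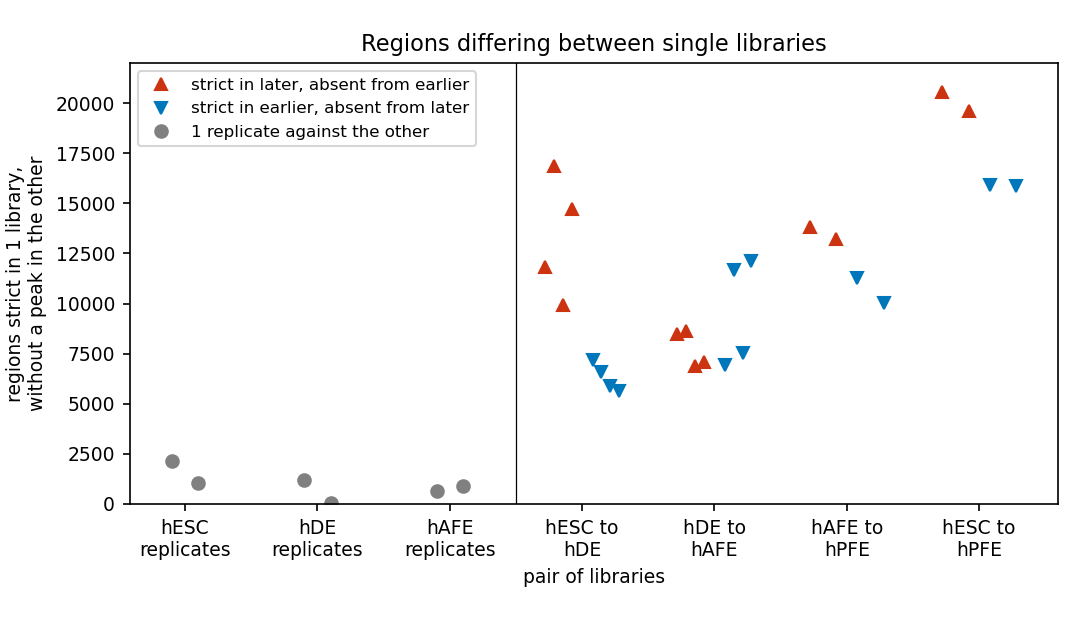
Number of regions that are strict in 1 library and have no peak in another, for each ordered pair of libraries: replicates of a stage (grey circles), later against earlier stage (red triangles) and earlier against later stage (blue triangles). Replicates differ by 61 to 2137 regions, and libraries of different stages in the 4 comparisons by 5637 to 20532.

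The 30 genes of the pluripotency list and the 30 of the definitive endoderm and mesendoderm list were set against 100,000 random lists matched on the number of regions per gene. The definitive endoderm list had 30 regions gained from hESC to hDE, at 14 genes, where 15.1 were expected, a ratio of 1.99 that did not pass (permutation test, two-sided, Benjamini-Hochberg adjusted p = 0.0816 over 144 tests). Its strict regions numbered 73 and 87 in hESC and 156 and 114 in hDE, so both hDE libraries lay above both hESC libraries. CXCR4 had 1 strict region in each hESC library and 5 in each hDE library, FOXA2 had 2 and 6 in hESC and 11 and 8 in hDE, GATA6 had 1 and 1 and then 8 and 5, and SOX17 had 3 and 2 and then 7 and 4. The pluripotency list had 7 lost regions where 2.48 were expected, a ratio of 2.82 (permutation test, adjusted p = 0.426). Without hESC replicate 1 this passed, with 24 against 7.14 expected (ratio 3.36, permutation test, adjusted p = 0.00288), and without hESC replicate 2 the ratio was 1.31. The ratio of the definitive endoderm list was 1.20 without hDE replicate 1 (permutation test, adjusted p = 1). Without hESC replicate 1 it passed at a ratio of 2.02 (permutation test, adjusted p = 0.0236), and without hDE replicate 2 at 2.20 (adjusted p = 0.0144). The 28 housekeeping genes had 45 and 48 strict regions in hESC, 46 and 31 in hDE, 44 and 44 in hAFE, and 54 in hPFE, and hDE replicate 2 had the fewest here and at the pluripotency list save for hPFE.

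From hDE to hAFE, 2656 regions were gained and 4152 lost, beside 21276 strict in all 4 libraries. Of the regions at EOMES and GATA6 gained in hDE, the strongest of each had no peak in hAFE. EOMES had 3 lost regions, GATA6 and PAX9 had 2 each, and CXCR4 had 1. FOXA2, GATA4, CXCR4 and EYA1, a gene of pharyngeal arch and pouch development, had 1 gained region each. The region at GATA4 lay 47704 bp outside the gene on chromosome 8 from 11628650 to 11629231, with fold enrichments of 11.9 and 7.29 in hAFE and no peak in the other 5 libraries. The region at EYA1 lay inside the gene on chromosome 8 from 71480255 to 71480652, with 11.8 and 7.27 in hAFE and likewise no peak elsewhere. The most gained regions, 4 each, were at WWC1, a gene of the Hippo pathway, and VPS41, followed by SGPP2, SGK1 and USP25 with 3. At SGK1 the strongest gained region, on chromosome 6 from 134378953 to 134379585, also had peaks in both hESC libraries (fold enrichments 11.6 and 15.8). The most lost regions were at FOXP2, with 6, and at SPOCK3, GPD2, RP1 and TNR, with 4 each. The SPOCK3 region, on chromosome 4 from 166670178 to 166671220, had fold enrichments of 12.7 and 21.2 in hDE and no peak in any other library. POU5F1, NANOG, SOX2, SOX17, PAX1, TBX1, HOXA3 and NKX2-3 had neither.

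Between single libraries, 6882 to 8654 regions were strict in hAFE and absent from hDE, and 6926 to 12141 were strict in hDE and absent from hAFE, against 61 to 1201 between replicates of these stages. No list passed. The anterior foregut endoderm list had 15 lost regions where 7.51 were expected (permutation test, adjusted p = 0.426), and the lung and thyroid list 12 where 4.83 were expected (adjusted p = 0.253). Both lists hold FOXP2, NKX2-1 and FOXE1, and the 6 lost regions of FOXP2 count in each, so these results are not separate. The hDE and hAFE libraries belong to different series. Of the gained regions 33.5% followed the series, with no peak in either hESC library and a peak in hPFE, and of the lost regions 11.7% did, with peaks in both hESC libraries and none in hPFE. A series difference that shows only at some stages would not split this way, so stage and series cannot be told apart at this step. Whether gain or loss was larger depended on the library and the definition: against hDE replicate 1, 8480 and 8654 regions opened and 6926 and 7552 closed, and against hDE replicate 2, 6882 and 7099 opened and 11682 and 12141 closed. With a summit of at least 10 times the background 4197 were gained and 3139 lost, and with a −log10 q of at least 5 the numbers were 14662 and 13348. The number gained was 4312 without hDE replicate 2 and 5667 and 5537 without hAFE replicates 1 and 2, the number lost was 9192 without hDE replicate 1, and 25,000 strict regions gave 599 and 1205 and 100,000 gave 10248 and 12162.

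**Figure D3:**
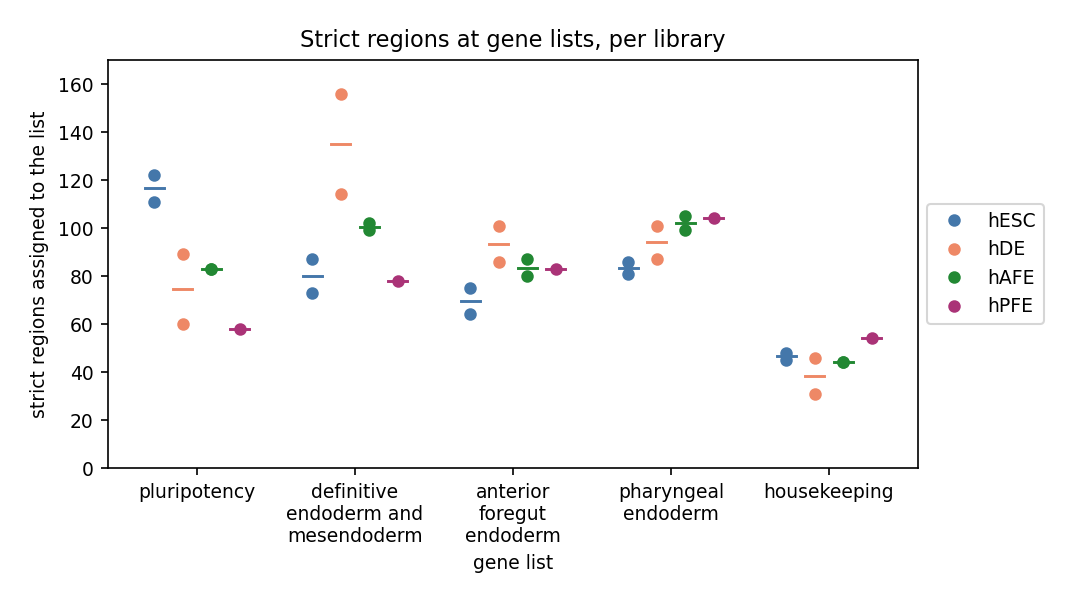
Number of strict regions assigned to the genes of 5 fixed lists, with 1 point per library and a bar at the stage mean (hESC, hDE and hAFE 2 libraries, hPFE 1). The pluripotency list goes from 111 and 122 regions in hESC to 58 in hPFE, and the definitive endoderm list peaks at 156 and 114 in hDE.

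The hPFE library differed from both hAFE libraries at more regions than the hAFE replicates differed from each other. Between single libraries, 13217 and 13806 regions were strict in hPFE and absent from an hAFE library, and 10026 and 11269 were strict in hAFE and absent from hPFE, against 653 and 889 between the hAFE replicates. Against both hAFE libraries together, 10959 regions were gained and 5418 lost, beside 22762 strict in all 3. Which of these was larger depended on the definition of strict: with a summit of at least 10 times the background 4470 were gained and 8036 lost, and with a −log10 q of at least 5 the numbers were 26843 and 27802. PAX9 had 2 gained regions and GATA6 had 1. The PAX9 region, on chromosome 14 from 36718290 to 36718569 and 38928 bp outside the gene, had a fold enrichment of 7.91 in hPFE and no peak in the other 6 libraries. EYA1 had 4 lost regions. GATA4, EOMES, CXCR4 and NKX2-3 had 1 each. The NKX2-3 region lay 24030 bp outside the gene on chromosome 10 from 99560554 to 99561080, with fold enrichments of 12.6 and 7.27 in hAFE. POU5F1, NANOG, SOX2, SOX17, FOXA2, PAX1, TBX1 and HOXA3 had neither. The most gained regions were at SEMA3D, an axon guidance gene, with 8, at MYOCD, a coactivator of cardiac and smooth muscle genes, and RUNX1, a transcription factor of blood formation, with 7 each, and at SETBP1 and EFNA5 with 6 each. The RUNX1 region, inside the gene on chromosome 21 from 34950609 to 34951321, had a fold enrichment of 10.6 in hPFE and no peak elsewhere. The most lost regions were at PLCB1 and IGSF11, with 5 each, and at WT1, STARD13 and ROR1 with 4 each. At WT1 the region on chromosome 11 from 32358741 to 32359162 had fold enrichments of 20.1 and 22.3 in hAFE.

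The 30 genes of the pharyngeal endoderm list did not stand out at the last step. They had 11 gained regions where 19.4 were expected (ratio 0.566, permutation test, adjusted p = 0.654) and 15 lost where 10.1 were expected (ratio 1.49, adjusted p = 0.867). Their strict regions numbered 81 and 86 in hESC and 104 in hPFE, and each hDE and hAFE library lay above both hESC libraries. PAX9 had 3 and 5 strict regions in hAFE and 9 in hPFE, a number hDE had as well (9 and 9). PAX1 had 5 and 5 in hAFE and 8 in hPFE, TBX1 had 2 and 0 and then 2, HOXA3 had 0 and 1 and then 3, and EYA1 had 7 and 6 and then 2. There was no replicate of hPFE, so no difference at this stage has a replicate check. A gained region needed 1 strict library here and 2 at the earlier steps, so the numbers gained are not comparable in size with those of earlier steps. The counts between single libraries need 1 library on each side at every step, but the libraries differ in depth (background 2.11 to 7.94), so these counts were set against replicates and not between steps. The number lost was 10026 and 11269 without hAFE replicates 1 and 2, 25,000 strict regions gave 3449 gained and 1186 lost, and 100,000 gave 31776 and 20315.

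Over the whole course from hESC to hPFE, pluripotency genes lost more open regions than matched random genes. The pluripotency list had 32 regions lost, at 19 of its 30 genes, where 14.3 were expected, a ratio of 2.23, and it was the only list of 18 to pass in any of 144 tests (permutation test, two-sided, p = 0.000260, Benjamini-Hochberg adjusted p = 0.0374). Of the 144 tests 12 had an unadjusted p below 0.05, where chance gives 7.2. Its strict regions numbered 111 and 122 in hESC, 89 and 60 in hDE, 83 and 83 in hAFE and 58 in hPFE. MYCN, SFRP2, a secreted WNT modulator, and DPPA4 had 3 lost regions each, and NANOG had 2. NANOG, a core pluripotency factor, had 3 strict regions in each hESC library, 1 and 0 in hDE and none in hAFE or hPFE. Strict is a rank within a library, and the lowest strict −log10 p was 8.89 in hESC replicate 1 and 97.1 in hDE replicate 2. These counts therefore do not measure closing alone. The region over a NANOG end, from 7789183 to 7789516 in hDE replicate 2, had a fold enrichment of 9.56 there without being strict. In hESC it had 4.78 and 7.93. At the other NANOG end, hDE replicate 2, hAFE replicate 2 and hPFE kept peaks that were not strict (7.87, 6.80 and 4.47). A region beyond that end of NANOG, on chromosome 12 from 7806907 to 7807302 in hDE replicate 1, was strict in all libraries but hDE replicate 2, where it had a peak. It is not in the count of strict NANOG regions, since an end of SLC2A14 is nearer. The strongest lost region of NANOG lay 1243 bp outside the gene on chromosome 12 from 7787490 to 7788159. The fold enrichment there was 7.73 and 12.4 in hESC, 3.49 and 4.68 in hDE and 6.83 and 3.30 in hAFE, with no peak in hPFE. DPPA4 had 7 and 6 strict regions in hESC, 4 and 4 in hDE, 0 and 1 in hAFE and 0 in hPFE. The SFRP2 region lay 829 bp outside the gene on chromosome 4 from 153789912 to 153790564, with fold enrichments of 5.29 and 6.22 in hESC and no peak from hDE on. The list had 12 gained regions where 28.7 were expected, a ratio of 0.418 that did not pass (permutation test, adjusted p = 0.0816) and that passed under 4 alternatives, among them without hESC replicate 1 (adjusted p = 0.0166). POU5F1 had 2 lost regions and also 2 gained, and SOX2 had 1 gained and none lost. The hESC and hPFE libraries belong to different series and hPFE is 1 library, so stage, series and library cannot be told apart in this call. It rests on hESC replicate 2, without which the ratio was 1.50 (permutation test, adjusted p = 0.354), and it also ended under 6 other alternatives. The ratio was then 2.24 with 25,000 strict regions, as large as in the main test, 1.53 with 100,000, 1.67 with the −log10 q threshold, 1.99 with a summit of at least 10 times the background, 2.50 with genes within 20 kb and 1.82 with regions over 1 kb from gene ends alone. The adjusted p ranged from 0.00102 to 0.864 over 18 alternatives, 11 of which passed. Those 11 include leaving out each hDE or hAFE library, which does not enter this comparison. These runs repeated the main 32 against 14.3 expected and are no check of the call.

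In numbers, 17319 regions were gained from hESC to hPFE and 8581 lost, beside 18647 strict in all 3 libraries. Of the stage markers, PAX9 had 4 gained regions, GATA6 and PAX1 had 3 each, and EOMES and CXCR4 had 1 each. The PAX1 region, on chromosome 20 from 21761646 to 21762169 and 43165 bp outside the gene, had fold enrichments of 10.1 in hPFE and of 4.04 and 3.30 in hAFE. EOMES, EYA1 and NKX2-3 had 1 lost region each, and SOX17, FOXA2, GATA4, TBX1 and HOXA3 had neither. The genes with the most gained regions were RUNX1 and UACA, with 10 each, and STXBP6, PRICKLE2, a planar polarity gene, and FGD4, with 9 each. Those with the most lost regions were PRR16 and TDRD3, with 7 each, and THRB, CCDC85A and MGST2, with 6 each. Between single libraries, 19585 and 20532 regions were strict in hPFE and absent from hESC, and 15871 and 15906 the reverse, against 1040 and 2137 between the hESC replicates. The number lost was 15871 and 15906 without hESC replicates 1 and 2. With 25,000 strict regions the numbers gained and lost were 6288 and 2325, and with 100,000 they were 43375 and 23834. With a summit of at least 10 times the background they were 7818 and 7284, so the excess of gain was then small.

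**Figure D4:**
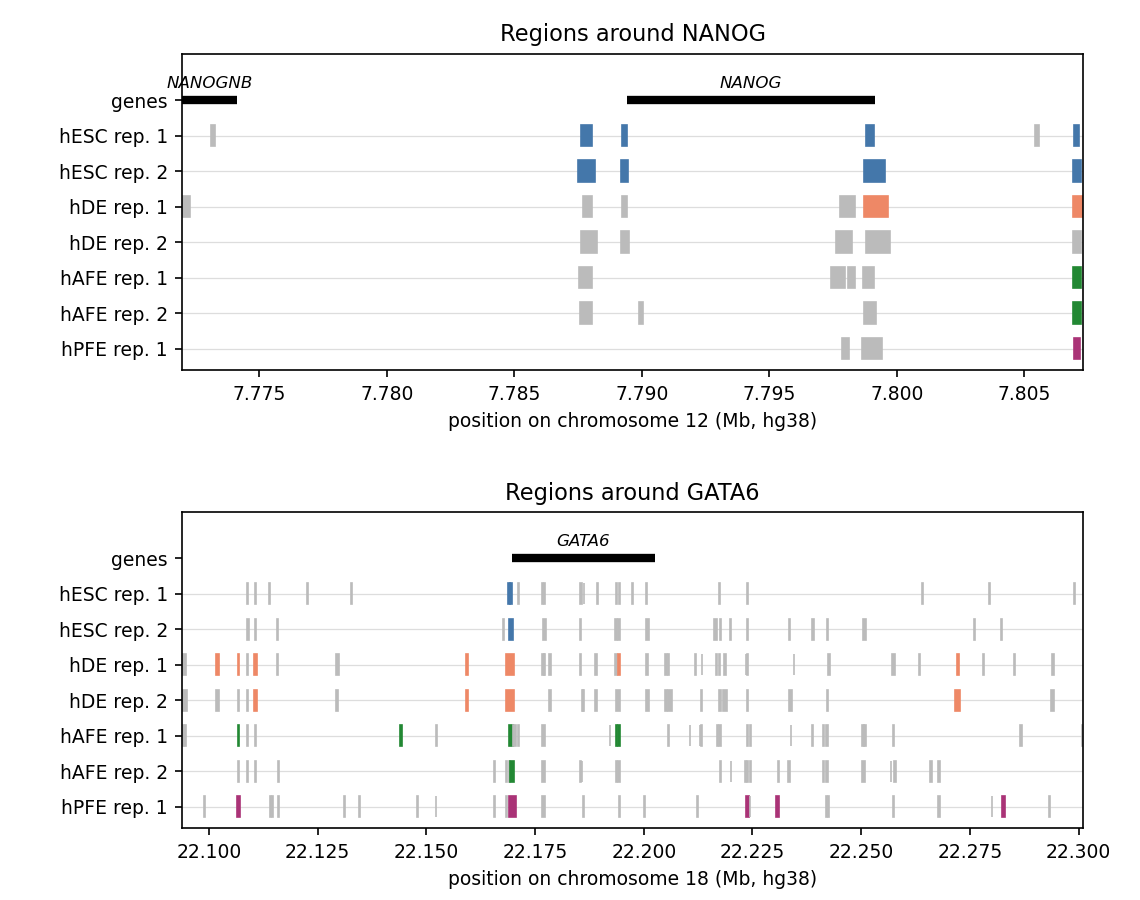
Regions of each library around NANOG on chromosome 12 and GATA6 on chromosome 18 (x axis, position in Mb of hg38), with 1 row per library, strict regions in the colour of the stage, other deposited regions in grey and protein-coding gene spans in black. The region outside the NANOG span, from 7787490 to 7788159, is strict in both hESC libraries and missing in hPFE, and the GATA6 region from 22158993 to 22159579 is present only in the 2 hDE libraries.

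The number of stage-specific regions needed 1 strict library for hPFE and 2 for the other stages. The hPFE number is therefore not comparable in size with the others. Regions strict in all libraries of 1 stage and absent from all others numbered 793 for hESC, 2580 for hDE, 772 for hAFE and 8095 for hPFE, the last from 1 library. Strict in every one of the 7 libraries were 14587 regions. Shared by neighbouring stages alone were 128 regions of hESC and hDE, 326 of hDE and hAFE, and 395 of hAFE and hPFE. A further 525 were strict in hESC, hDE and hAFE and absent from hPFE, and 158 were strict in hDE, hAFE and hPFE and absent from hESC. Of the 7050 regions gained in hDE, 40.7% had no peak in either hAFE library and 76.3% had none in hPFE, while 9.97% were strict in both hAFE libraries. Whether this opening was transient cannot be told, since the series also changes after hDE. The hAFE libraries were also shallower (background 2.22 and 3.85, against 4.58 and 7.94 in hDE), which makes absence easier. Of the 2656 regions gained in hAFE, 28.1% were strict in hPFE and 40.7% had no peak there, and 62.5% had no peak in either hESC library. Of the 10959 gained in hPFE, 86.0% had no peak in either hESC library and 82.2% had none in either hDE library. Leaving out 1 library moved the number for hESC to 2125 and 2281 without hESC replicates 1 and 2, that for hDE to 5738 without hDE replicate 1, and that for hAFE to 1797 and 2263 without hAFE replicates 1 and 2.

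Regions that opened or closed lay away from gene ends. Of the regions gained or lost in the 4 comparisons, 1.52% to 3.55% had an end of a protein-coding gene within 1 kb. The share was 45.9% to 57.3% of the regions strict in both stages, 63.5% of the 14587 strict in every library, and 12.5% of all 129726 regions. The stable regions were also wider, with medians of 1014 to 1109 bp against 435 to 762 bp. The odds ratios against the stable regions were 0.0163 to 0.0403 (Fisher's exact test, two-sided, p at most 1e-300 in each of the 8 tests), and regions are not replicates. Stable regions had to be strict in every library compared, and changed regions had to lack any peak at 1 stage. The size of these ratios therefore reflects the definitions too. The share was below 4% in each of the 8 sets. Of the regions gained from hESC to hDE, 1.66% lay near a gene end, 40.2% elsewhere inside a gene span and 58.1% between genes. Of those gained from hAFE to hPFE, 1.83% lay near a gene end and 53.2% between genes. Per library, 25.7% to 26.7% of strict regions lay near a gene end in 6 libraries, and 21.1% in hDE replicate 2. That library also had the lowest share of strict regions on chromosomes 17, 19 and 22, which are rich in genes, at 6.09% against 8.18% to 11.3% in the others. Gene spans carry no strand here, so the 2 ends of a gene were treated alike and promoters were not told from gene ends.

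The remaining lists gave no call in the main test. Under alternatives, neural ectoderm (lost) and Nodal and BMP signalling (gained) passed from hESC to hDE with a summit of at least 10 times the background, and anterior HOX genes (lost) without hESC replicate 1. In addition to the lists above, the lowest adjusted p was 0.532 for epithelial adhesion and EMT, 0.654 for WNT and FGF signalling, 0.730 for anterior HOX genes and cofactors, 0.789 for Nodal and BMP signalling, 0.820 for mesoderm and heart, and 0.866 for liver and pancreas. It was 0.867 for retinoic acid pathway, neural ectoderm, neural crest and non-neural ectoderm, blood and endothelium, extraembryonic and housekeeping genes, and 0.897 for posterior gut and posterior HOX genes. Genes of the epithelial list had 59 and 74 strict regions in hESC, 80 and 59 in hDE, 87 and 77 in hAFE and 96 in hPFE. Those of the posterior list, which mark hindgut, had 33 and 28 in hESC, 27 and 25 in hDE, 22 and 24 in hAFE and 16 in hPFE. Genes of the retinoic acid pathway had 52 and 71, 57 and 44, 54 and 65, and 61. Simulated data were drawn at the mean rate of gain from hESC to hDE, independently for each region. Of the tests of seeded lists, 20 of 32 were called with a 2-fold excess and 32 of 32 with a 3-fold excess. With no excess 0 of 32 were called. Other excesses, the other comparisons and changed regions that cluster at genes were not simulated, so the power in the real data may be lower.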

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

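Added after seeing the data were absence below 4 times the background, a strict summit of at least 10 times the background and lists from regions over 1 kb from gene ends. Of 285 values under the alternatives, 183 kept their direction and side of the threshold or stayed within 1.5 times the main count, 87 counts moved further, 7 list results no longer passed the threshold, 8 newly passed it, and no tested ratio or odds ratio changed direction. The balance of gained and lost regions did turn from hDE to hAFE and from hAFE to hPFE. The excess of similarity within stages held under every alternative, from 0.0924 to 0.226, and every odds ratio of gained or lost regions near gene ends stayed between 0.00560 and 0.0788. Motif alternatives were not run, and a replicate block of the stage patterns has no definition of its own. Counts of regions follow the number called strict by construction. Depth differs by 3.76 times between libraries, and the lists end at different levels, so absence is weaker evidence in a shallow library.

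Numbers gained and lost are given in the order hESC to hDE, hDE to hAFE, hAFE to hPFE and hESC to hPFE. With 25,000 strict regions, 2465, 599, 3449 and 6288 were gained, 287, 1205, 1186 and 2325 were lost, and 7995 were strict in all libraries. With 100,000, the numbers were 17358, 10248, 31776 and 43375 gained, 6717, 12162, 20315 and 23834 lost, and 26495 in all. With a −log10 q of at least 5, which 100% of the regions of hDE replicate 2 passed, they were 18656, 14662, 26843 and 37738 gained, 4907, 13348, 27802 and 18593 lost, and 26043 in all. With absence from the top 100,000, 5614 were gained from hDE to hAFE and 16501 from hAFE to hPFE, and 3989, 7979 and 8695 were lost over the first, second and last step. With a summit of at least 10 times the background, 4197 were gained from hDE to hAFE, 4470 from hAFE to hPFE and 7818 from hESC to hPFE, and 3139, 8036 and 7284 were lost. Here and with the −log10 q threshold, gain was the larger from hDE to hAFE (main 2656 and 4152) and loss from hAFE to hPFE (main 10959 and 5418). Without hAFE replicate 2 the former were 5537 and 5534. With absence below 4 times the background, 8807 were lost from hAFE to hPFE.

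Leaving out each library in turn gave 8087 to 12917, 3435 to 5667, 13217 to 13806 and 19585 to 20532 gained regions and 2267 to 4235, 5241 to 9192, 10026 to 11269 and 15871 to 15906 lost. Fewer libraries then had to meet the definition, so the numbers grow by construction.

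Same-numbered replicates did not deviate together (correlations of −0.0199, −0.0545 and 0.0217 between stages), so the numbers were not taken to pair the libraries. With a replicate block, the similarity difference was 0.165, and the numbers between stages of 2 libraries did not move. With hPFE the block leaves 1 pair, and 11269 were lost from hAFE to hPFE and 15906 from hESC to hPFE.

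The number of list calls, 1 in the main test, was 0 with 100,000 strict regions, with the −log10 q threshold, and with regions over 1 kb from gene ends. It was 2 with windows of fixed width and with any gene end within 50 kb, 4 with absence from the top 100,000 and with Fisher's exact test on regions, and 5 with a summit of at least 10 times the background. Leaving out libraries gave 0 calls (without hESC replicate 2) to 5 (without hESC replicate 1). The loss at the pluripotency list from hESC to hPFE passed under 11 of 18 alternatives, with a ratio from 1.50 to 2.50. It did not pass with 25,000 strict regions (ratio 2.24, permutation test, adjusted p = 0.864), with 100,000 (1.53, 0.173), with the −log10 q threshold (1.67, 0.341), with a summit of at least 10 times the background (1.99, 0.0739), with genes within 20 kb (2.50, 0.0590), with regions over 1 kb from gene ends (1.82, 0.348) and without hESC replicate 2. The gain at the definitive endoderm list from hESC to hDE passed under 7 of 18, with ratios from 1.20 to 3.11. The definitive endoderm list also passed for regions lost from hDE to hAFE with absence from the top 100,000 (39 against 17.1 expected) and with a summit of at least 10 times the background (22 against 8.04). With that summit, the lists of anterior foregut endoderm (lost from hDE to hAFE, ratio 2.57), neural ectoderm (lost from hESC to hDE, 3.69) and Nodal and BMP signalling (gained from hESC to hDE, 2.24) passed as well. Without hESC replicate 1, the pluripotency list (ratio 3.36) and the anterior HOX list (3.89) passed for regions lost from hESC to hDE. The shortage of regions gained at the pluripotency list from hESC to hPFE passed with absence from the top 100,000, windows of fixed width, genes within 20 kb and without hESC replicate 1. With Fisher's exact test on regions, anterior foregut endoderm and lung and thyroid passed for regions lost from hDE to hAFE.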

Other observations

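The tests of the 2 series in the last paragraph were chosen after their result was seen, and the others before. Strict regions at genes of the fixed lists also moved in ways that no test called. At CXCR4 the set of regions changed from step to step: a region on chromosome 2 from 136136892 to 136137512 was present only in hDE, and one from 136176633 to 136177200 opened in hAFE, with fold enrichments of 8.08 and 6.29, and had a peak in hPFE that was not strict (3.15). A region from 136125801 to 136126738 had peaks in both hDE and both hAFE libraries and in hESC replicate 2, and none in hPFE. At GATA6 the region from 22106511 to 22107103 on chromosome 18 had no peak in hESC, fold enrichments of 4.17 and 5.54 in hDE, 10.9 and 5.33 in hAFE, and 11.1 in hPFE. At PAX9, with 9 strict regions in each hDE library and in hPFE, the sets overlapped in part: the region from 36720509 to 36721092 on chromosome 14 was present only in hDE and that from 36718290 to 36718569 only in hPFE. The region from 36773542 to 36774038 had fold enrichments of 5.48 and 8.62 in hDE, 3.41 in hAFE replicate 1 and 9.74 in hPFE.

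The hPFE library differed from the hAFE libraries at more regions than replicates differed from each other. Weak and noisy peaks in hPFE are argued against for its 10,000 strongest regions. Of these 6.40% had no peak in hAFE replicate 2, the closer library, and at most 0.0300% of such regions were missing between replicates. The test did not reach the weaker strict regions, and weak peaks remain open there. The 10959 gained regions had a median width of 435 bp. The strict hPFE regions had the lowest median summit, 11.7 times the background, against 13.3 to 33.8 times in the other libraries. Mesenchymal cells in the culture remain open: the mesenchyme list had 26 gained regions where 18.5 were expected, a ratio of 1.41 (permutation test, two-sided, p = 0.120), with COL5A1 at 4 and 14 of its 28 genes at none, COL6A3 went from 4 and 3 strict regions in hAFE to 0, and 8 of the genes are also in the fixed lists. Its strict regions numbered 78 and 83 in hAFE and 90 in hPFE, within the range of the other stages (81 to 94). A difference between preparations or cultures of the hPFE library cannot be told apart from the stage, a biological and untested candidate explanation, since there is 1 library.

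Replicate 2 of hDE had 4.80 percentage points fewer strict regions near gene ends than the lowest other library. The limit on the number of peaks is argued against, since it cut only weak peaks. The weakest deposited −log10 p of this library was 8.86, and the lowest strict one was 97.1. The limit reached neither the strict regions nor the 10,000 strongest, so the shortfall among the latter is no further test of it. Among the 10,000 strongest regions of each library the shortfall was 15.3 points (39.99% against 55.3% in hESC replicate 2). Depth remains open, since it bears on the ranking at every rank. This library had the highest background (7.94). The share was 58.8% in hPFE (background 5.66), 55.3% in hESC replicate 2 (4.62) and 63.4% in hDE replicate 1 (4.58). In the shallower libraries it was 60.2% to 65.7%. The strict regions of this library were the widest (median 769 bp). Wider regions reach a gene end more easily, so width could not give a shortfall. With windows of fixed width the shortfall was 4.95 points. No biological explanation was tested, as the design gives none for 1 of 2 replicates. A difference between preparations was not tested.

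Between hDE and hAFE, the stage changes together with the series. A difference between the 2 series that acted alike at every stage would leave the hESC libraries like hDE and the hPFE library like hAFE. Of the 2656 gained regions 33.5% had no peak in either hESC library and a peak in hPFE, and of the 4152 lost regions 11.7% had peaks in both hESC libraries and none in hPFE. These shares cannot decide whether a difference of that kind caused most of either set, since a region closed in hESC or hPFE for another reason may be barred from counting. A series difference that shows only at some stages would not split this way and was not tested. Of the lost regions 69.2% had no peak in either hESC library, so they could not count as split whatever their cause. Likewise, 40.7% of the gained regions had no peak in hPFE and could not count. Stage and series therefore cannot be told apart in this comparison.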
